A study of Citrus sinensis with 6 samples.

How the data were processed

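Transcript abundance was measured by RNA sequencing of sweet orange (Citrus sinensis) leaf tissue in 6 libraries, 3 from leaves inoculated with the fungus Lecanicillium psalliotae and 3 from leaves that received sterile water. Per the labels, detached leaves were surface-disinfected in 4% sodium hypochlorite, pricked at 6 points and given 3 µl of spore suspension or water per point. Incubation took 14 days without light at 26 °C, and tissue within 2 cm of the lesions was then collected. The control leaves were therefore wounded in the same way. The growth protocol gives 30 µl per leaf where the points add up to 18 µl, and the difference was left unresolved. A cell type entry in the labels that names an animal cell was disregarded. The labels give 3 leaves per group but do not state that each library came from its own leaf or plant, so p-values measure the spread between these libraries.

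The authors deposited 1 table of FPKM values (fragment counts normalised to gene length and to mapped fragments, a unit given by the file name) with 1 column per library and 30540 rows. Of these rows, 29875 have IDs that start with Cs_ont and 665 have IDs that start with new_gene. The aligner, quantification tool, genome build and annotation are not given in the sources used here, and neither is what the new_gene rows are. Every column matched the description of 1 sample, and no column belonged to another sample. Groups and replicate numbers were taken from the sample titles.

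No reference genome was used, and the files do not pair the IDs with gene names. The gene table of the Valencia sweet orange RefSeq assembly held 0 of the 30540 IDs. The 30 lists of gene functions fixed before the data were examined (defence, hormone, photosynthesis and cell type genes among them) could therefore not be tested, nor could the planned set tests on them. For the same reason genes are reported by ID, without function, position or transcript structure, and RNA quality could not be checked with organelle-encoded genes.

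FPKM values carry no read counts, so no count model was fitted. The depth in reads is unknown, but low values moved in steps that gave relative depths. For genes with a mean under 0.2 FPKM, the log2 ratio between libraries was searched for the offset that collected the most genes within 0.005, counting also the offsets 1 higher and 1 lower. Taking control replicate 1 as 1, the relative depth was 0.496 in control replicate 2 and 0.431 in control replicate 3. It was 0.689, 0.562 and 0.54 in infected replicates 1, 2 and 3. Against control replicate 1, 23 to 31 of 1476 to 1791 compared genes fell on the chosen step. An average window held 2.77 to 3.22 genes. Most low genes were off the step, so these depths are estimates. For control replicate 3 an offset 1 lower collected more genes (28 against 23), and the comparison with control replicate 2, where 43 genes fell on a step of 0.2, decided between them.

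Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an empirical Bayes mean-variance trend, 2 groups, no covariate and two-sided p-values adjusted by the Benjamini-Hochberg method. Rows with a mean of at least 1 FPKM over the 6 libraries were tested (15661 rows), and an adjusted p under 0.05 was called. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The method was tested on simulated data with the control means and pooled residual spreads of the 15661 rows, drawn independently for each gene. The 200 changed genes per run were drawn only from rows above 5 FPKM in control leaves. Of these, 64% of those changed 2-fold and 89.2% of those changed 4-fold were recovered over 5 runs, with 6.34% false calls. Recovery of lower genes was not tried. Without any change the method made 0 calls. The simulation gave each gene the same spread in both groups. In the data the infected libraries spread more (median SD 0.186 against 0.128 on the log2 scale). The rates under unequal spread or between correlated genes were not tried, so they may differ in the real data.

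The genes named were those with the largest changes in each direction (2 higher and 2 lower) among called genes with at least 5 FPKM in the higher group and no overlap between groups. That is the rule set for the case of IDs without names. The row with the highest mean FPKM over the libraries was singled out after its values were seen.

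Alternatives covered the pseudocount, the low-value filter, scaling between libraries, the variance model, sample weights, the replicate number as a block and leaving out each library. Whether equal replicate numbers pair the libraries was checked by correlating deviations from the group means. The correlations were 0.099, 0.23 and -0.12 for numbers 1, 2 and 3, which cannot decide it with 3 libraries per group. The labels do not state pairs, so the main test treated the libraries as unpaired. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.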

Results

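The comparison addressed how gene expression in sweet orange leaves differed 14 days after inoculation with Lecanicillium psalliotae, a filamentous fungus, from that in wounded leaves given water. Each group held 3 libraries. Between 15460 and 15721 genes were above 1 FPKM per library, and the median FPKM of the tested genes lay between 13.5 and 14.6. The number of genes listed at 0 ran from 9658 in control replicate 1, the deepest library by relative depth, to 10389 in control replicate 3, the shallowest.

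The row new_gene186 had the highest mean FPKM over the 6 libraries. It held 31.6% ± 6.62 of the summed FPKM in control leaves and 16.4% ± 7.06 in infected leaves (SD, n = 3 each). The shares did not overlap, but the two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 can give. Its log2 fold change of -1.24 (SE 0.519) did not pass the test (limma, adjusted p = 0.262). The lowest share, 8.99%, was in infected replicate 1 and the highest, 39.1%, in control replicate 3. FPKM divides by gene length, so these shares are not shares of reads.

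The libraries separated by treatment on the first principal component, which held 40.3% of the variance. The second component, with 27.5%, separated infected replicate 1 from infected replicate 2. Pearson correlations of log2(FPKM + 1) across the tested genes were 0.973 to 0.981 within the control group. Between control and infected libraries they were 0.951 to 0.969. Infected replicate 3 correlated at 0.975 with infected replicate 1 and at 0.977 with infected replicate 2, above that range, while infected replicates 1 and 2 correlated at 0.954, within it. The median SD per gene on the log2 scale was 0.128 in control leaves and 0.186 in infected leaves.

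**Figure D1:**
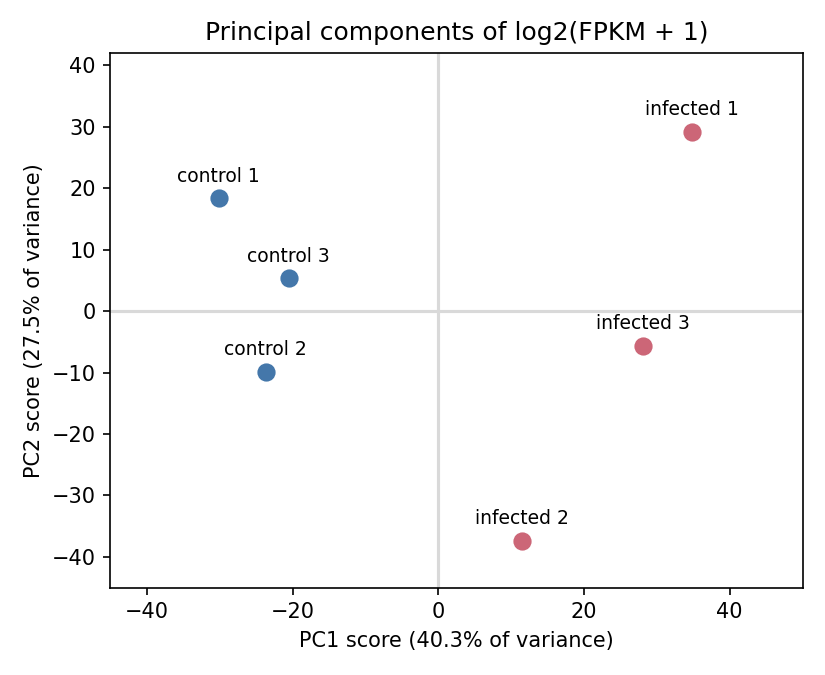
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1), over the 15661 tested genes, in log2 units (blue, control; red, infected). Control libraries lie at -20.5 or below on the first component and infected libraries at 11.4 or above, while the second component runs from -37.4 for infected replicate 2 to 29.1 for infected replicate 1.

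Infected leaves differed from control leaves in 85 of 15661 tested genes, of which 59 rose and 26 fell (limma, adjusted p under 0.05). In all 85 the 3 infected values lay outside the range of the 3 control values, which selection by a small p-value favours. The genes that rose went from a median of 13.7 FPKM in control leaves to 35.4 FPKM in infected leaves, with a median log2 fold change of 1.16. The genes that fell went from a median of 13.8 to 4.61 FPKM, with a median log2 fold change of -1.13. Of the called genes, 58 changed at least 2-fold, 41 of them upwards and 17 downwards.

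The gene Cs_ont_2g005610 showed the largest called rise. It stood at 0.331 ± 0.342 FPKM in control leaves and 11.7 ± 6.30 FPKM in infected leaves (SD, n = 3 each), with a log2 fold change of 3.17 (SE 0.365, limma adjusted p = 0.038). Its control level was under 1 FPKM, and with a pseudocount of 0.1 the log2 fold change was 5.01 (limma adjusted p = 0.0546). The row new_gene13 rose from 4.70 ± 0.937 to 43.3 ± 14.2 FPKM, 9.21 times the control mean (log2 fold change 2.92, SE 0.241, limma adjusted p = 0.0171). The call for Cs_ont_2g005610 was lost without any one library other than infected replicate 1, at limma adjusted p of 0.0647 to 0.132, with log2 fold changes of 2.79 to 3.36. That for new_gene13 was lost without control replicate 1, 2 or 3 or infected replicate 3, at limma adjusted p of 0.0538 to 0.104, with log2 fold changes of 2.79 to 3.03.

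The gene Cs_ont_6g018240 showed the largest called fall, from 15.2 ± 5.45 FPKM in control leaves to 1.69 ± 0.526 FPKM in infected leaves (SD, n = 3 each). The control mean was 9.01 times the infected mean (log2 fold change -2.56, SE 0.260, limma adjusted p = 0.0322). The row new_gene616 fell from 76.4 ± 9.82 to 18.6 ± 1.80 FPKM, a control mean of 4.10 times the infected mean (log2 fold change -1.97, SE 0.130, limma adjusted p = 0.0102). The call for Cs_ont_6g018240 was lost without any one library other than infected replicate 1, at limma adjusted p of 0.0554 to 0.147, with log2 fold changes of -2.70 to -2.30. That for new_gene616 was lost without control replicate 1 or 3 or infected replicate 3, at limma adjusted p of 0.0523 to 0.082, with log2 fold changes of -1.92. The functions of these 4 genes are not known from the files.

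**Figure D2:**
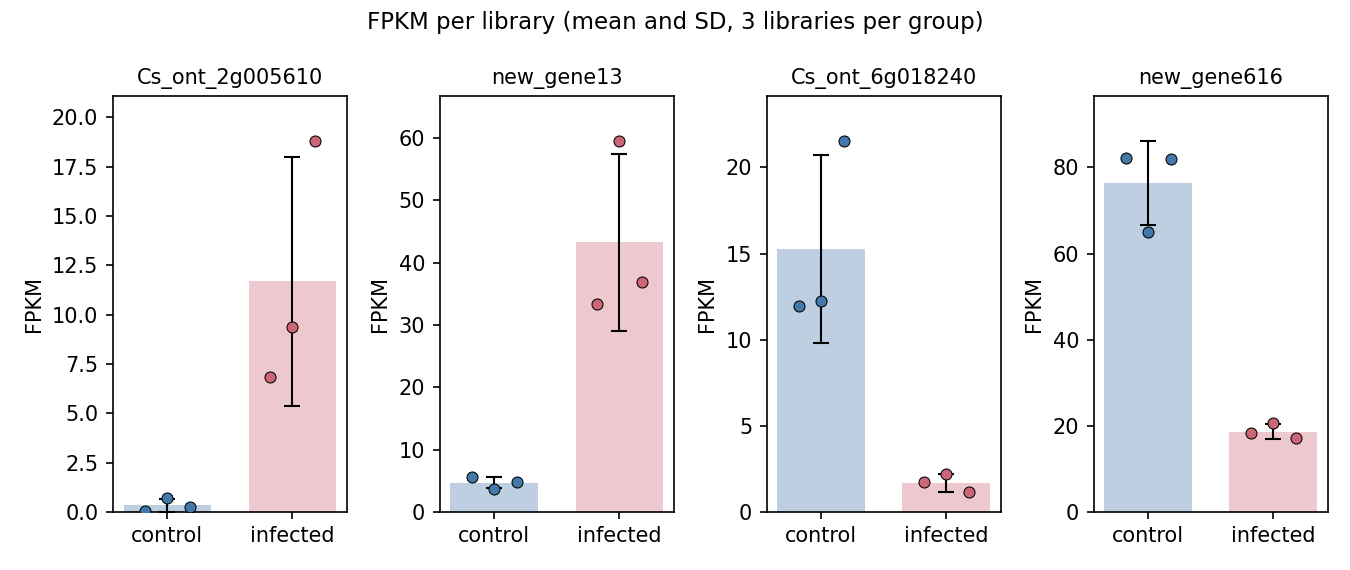
FPKM of the 4 named genes in each library (points), with the group mean (bars, from 0) and SD (error bars) for 3 control and 3 infected libraries; each panel has its own scale. By the rule that selected these genes, the infected points lie outside the range of the control points, for example 17.1 to 20.6 FPKM against 65.0 to 82.2 FPKM for new_gene616.

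The called genes came from most parts of the ID numbering. The series numbered 2g, with 1879 tested genes, gave 11 rises and 5 falls, and the series 6g, with 1395, gave 4 rises and 5 falls. The 665 new_gene rows gave 13 rises and 1 fall. All 665 passed the filter, against 15661 of all 30540 rows. With new_gene186 included, they held 55.3% to 62.3% of the summed FPKM in control libraries and 50.8% to 54% in infected libraries. Among the 87 tested rows of the Un series none was called, although their median log2 fold change was -0.22.

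Changes of at least 2-fold were more common than calls. Of the tested genes, 356 were at least 2-fold higher in infected leaves and 132 at least 2-fold lower, whatever their p-value, and 11.5% and 12.9% of these passed the test. The infected values all lay above the control values in 11.5% of tested genes and all below in 14.8%. Chance gives 5% for each direction on average over splits. These shares were not computed for the other splits, so how far a single split can stray from 5% is not known. At an unadjusted p under 0.05 there were 1505 higher and 1510 lower genes, 3015 in all. The mean expected for unchanged, independent genes is 783, and the 9 other splits of the 6 libraries into 3 and 3 gave 149 to 1911.

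**Figure D3:**
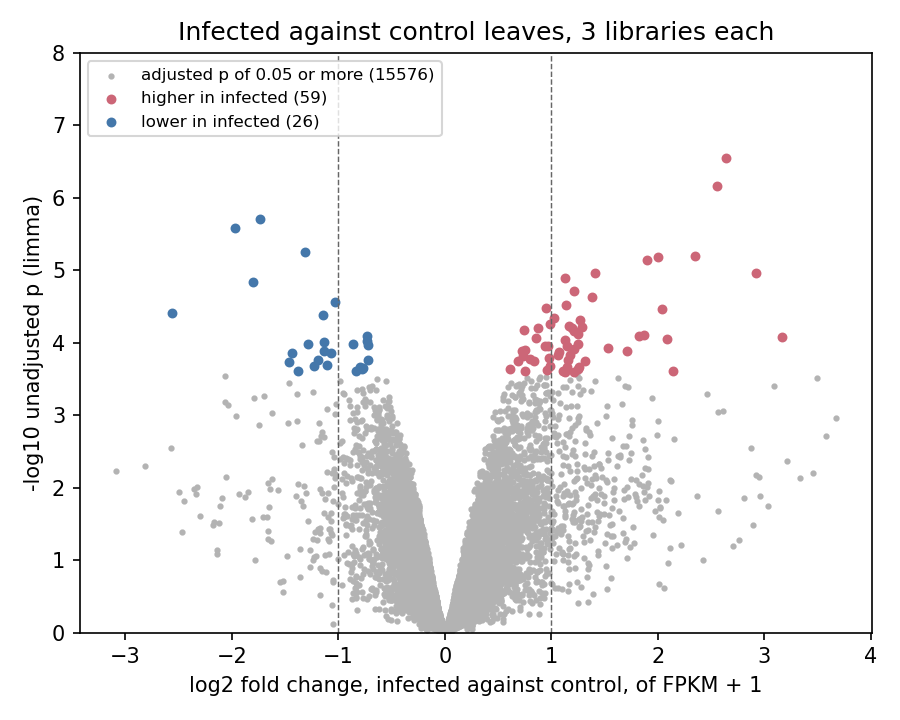
Log2 fold change of FPKM + 1, infected against control, on the x axis and -log10 of the unadjusted limma p on the y axis for each of the 15661 tested genes; dashed lines mark 2-fold. The 59 called rises (red) and 26 called falls (blue) sit at the top of the plot, and many genes beyond 2-fold (grey) lie below them.

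With 1 library fewer the count of calls was 5, 4 and 2 without control replicates 1, 2 and 3, and 350, 20 and 1 without infected replicates 1, 2 and 3. With the replicate number as a block the count was 0, and the 4 named genes had limma adjusted p of 0.103 to 0.109. The split of 59 rises and 26 falls became 377 and 30 when each library was scaled to the same FPKM sum, and 34 and 27 when new_gene186 was left out before that scaling, an alternative chosen after seeing the data. Falls outnumbered rises without infected replicate 1 (166 rises and 184 falls) and with estimated sample weights (3434 and 4016). In the infected group that weighting rests almost entirely on replicate 3, at 23.2 against 0.23 and 0.249 for replicates 1 and 2. Leaving out both control 1 and infected 1, also chosen after seeing the data, gave 19 rises and 33 falls.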

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

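The alternatives without new_gene rows, with new_gene186 left out and with 2 libraries left out were chosen after seeing the data. The count of 85 changed genes stayed within 1.5 times (57 to 91) under the other pseudocounts, filters and variance models, median-centring, trimmed-mean and quantile scaling, and without the new_gene rows. Scaling to equal FPKM sums gave 407 genes, 207 of them changed 2-fold, and moved the median log2 fold change of all tested genes from -0.0145 to 0.169; with new_gene186 left out first, these were 61 genes and -0.0828. The 58 genes changed 2-fold became 36 without a filter and 38 at a mean of at least 5 FPKM; the cause was not tested. Estimated sample weights gave 7450 genes, 699 of them 2-fold, with a weight of 23.2 for infected replicate 3 against at most 2.05 for the others. With control 1 and infected 1 left out, 52 genes passed, 12 of them among the 85. Leaving out 1 library gave 1 to 350 genes and 1 to 213 changed 2-fold, from fewer libraries; the 350 without infected replicate 1 included 83 of the 85. The replicate block called 0 genes, 0 of them 2-fold, with 3262 at an unadjusted p under 0.05 (limma) and fewer residual degrees of freedom. Deviations from the group means correlated best between control 2 and infected 2 (0.23), then between control 1 and infected 3 (0.17). With 3 libraries per group these correlations cannot tell whether equal numbers mark pairs. The labels do not state pairs, so the main test used none. The 4 named genes kept their direction in every setting run, and lost their call in 8 of 21 (Cs_ont_2g005610), 7 of 21 (Cs_ont_6g018240), 5 of 20 (new_gene13) and 4 of 20 (new_gene616). Of the 10 splits of the libraries into 3 and 3, the real one gave 85 genes (58 changed 2-fold) and the highest other 5 (5), 1 split reaching the real count; 10 splits cannot give a share under 0.05. Gene list tests were not run. Control replicate 3 had an estimated 0.431 of the depth of control replicate 1, which limits low genes most there.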

Other observations

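The tests on the new_gene rows, the Un rows and neighbouring IDs were added after the main result was seen, and the one on the Un rows after part of its own values was seen. Genes that set 1 library apart from all 5 others by at least 4-fold were few, and they lay mostly on the low side in control leaves. Control replicate 1 was below all others in 24 genes and above them in 1, control replicate 2 below in 15 and above in 1, and control replicate 3 below in 1 and above in 0. Infected replicate 1 was above all others in 7 genes and below in 0, infected replicate 2 above in 1 and below in 10, and infected replicate 3 above in 1 and below in 1.

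Rows with new_gene IDs were called higher in infected leaves more often than other rows, 13 of 665 (1.95%) against 46 of 14996 (0.307%; Fisher's exact test across genes, which are not independent, p = 8.64e-07). Under the scaling alternatives their share stayed above that of other rows, from 1.05% against 0.18% to 6.17% against 2.24%. Apart from quantile scaling, these shift all rows of a library nearly alike, so they say little about a difference between kinds of rows. Without infected replicate 1 their share was 2.86% against 0.98%, a smaller ratio than the 1.95% against 0.307% of the main test. The median log2 fold change of the new_gene rows went from 0.233 to 0.119. Other rows at matched expression were called higher less often than the new_gene rows (median 106 FPKM). Random draws of them held 1.92 called rises on average and at most 8 (permutation p = 1e-04, the smallest that 10000 draws can give). The draws treat rows as independent, which the new_gene rows are not, so the p-value cannot exclude expression level. An equal shift of all new_gene rows within a library could account for part. With it taken out, 5 rows were called higher and 7 lower. Matched draws, with the same limit, held 1.94 called rises on average (permutation p = 0.032). Of the 13 original calls, 4 were among those 5. A factor that moves many of these rows together by unequal amounts remains a candidate explanation. Their estimated correlation within groups was 0.175 against at most 0.0195 in 100 random sets of other rows. Those sets were not matched on expression, so they cannot tell such a factor from one tied to expression level. The set test with an estimated correlation gave p = 0.24 (camera, adjusted p = 0.945, and 1.13e-06 with the preset correlation of 0.01). The median level of the new_gene rows against control leaves was 0.493 in infected replicate 1 on the log2 scale. It was 0.0419 in infected replicate 2 and 0.182 in infected replicate 3, and inoculation itself also stays open.

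The 87 Un rows had a median log2 fold change of -0.22 and passed a set test with the preset correlation (camera, adjusted p = 0.000664 over 11 ID series), as only the new_gene rows did besides. These rows may share a factor within each library. Their estimated correlation was 0.231 against at most 0.089 in 100 random sets of other rows, which were not matched on expression. With the estimated correlation the set test gave p = 0.31 (camera, adjusted p = 0.945). The median level of the Un rows was -0.382, -0.0803 and -0.255 in infected replicates 1, 2 and 3. In control replicates 1, 2 and 3 it was 0.107, 0.0466 and -0.0741. Their median log2 fold change was negative under each scaling alternative, from -0.284 to -0.0538. Apart from quantile scaling, these alternatives shift all rows of a library nearly alike, so they say little about a difference between kinds of rows. What the Un rows encode was not determined, and an effect of inoculation on them stays open.

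Genes with consecutive IDs had slightly similar log2 fold changes across 9053 pairs (Pearson r = 0.0968, Spearman rho = 0.054). A chance order of the IDs is argued against by 100000 permutations, whose strongest r was 0.0534 (p = 1e-05, the smallest they can give). Neighbours were also alike where no fungus was present: the difference between control replicate 1 and the other controls gave r = 0.0825 (permutation p = 1e-05), although its Spearman rho was 0.0228, lower than the 0.054 of the infected difference. Among inoculated leaves, the difference between infected replicate 1 and the other infected libraries gave r = 0.0802 and rho = 0.0448. A similarity of neighbours that does not depend on inoculation is a candidate explanation for part of this, and reads shared between similar neighbouring genes were not tested. In 0 of the pairs were both genes called. With 85 called among 15661 tested genes such pairs would be rare by chance, so this shows little.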
